A study of Mus musculus with 8 samples.

How the data were processed

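RNA from pools of 8 aortic segments each, of newborn wild-type and fibulin-4 knockout mice of strain C57BL/6, was amplified from 5 ng of total RNA, labelled with biotin and hybridised to 8 Affymetrix arrays, per the labels' protocols. The authors deposited 1 value per probe set and array on a log2 scale, made with Affymetrix Expression Console and RMA, per the submitters' processing notes. Versions, genome build and probe set definition are not given in the sources used here. RMA corrects background, normalises probe intensities between arrays and summarises probes by a robust fit, which leaves dim genes with compressed differences. The deposited medians and quartiles still differed between arrays, so the distributions were compared and 2 further scalings were tried.

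The table held 41345 probe sets. The platform annotation gave 1 gene symbol to 23521 of them and several to 1814, and 16010 were not named there; only probe sets with 1 symbol were used in the main tests. Of these, 23328 matched a gene of the RefSeq annotation of assembly GRCm38.p6 by gene identifier, and 0 symbols needed updating. The probe set with the highest mean over all arrays was kept for each of 1082 genes with several, which left 22180 genes. No coordinates are printed, because the build of the array design is not given. The targeted gene was not analysed here.

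The log2 values were fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 4 groups over all 8 arrays, so that every comparison shares 1 estimate of the spread (4 residual and 5.52 prior degrees of freedom). The comparisons were the effect of the knockout in each segment, its average over both segments, the segment difference (ascending minus descending) in each genotype, and the difference of the knockout effect between segments. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Array numbers are shared between groups, but the labels do not say that they pair pools, so no block was used in the main fit.

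Before the data were examined, 46 lists of genes of pathways and of cell types that the dissected tissue could hold were fixed; 843 of their 930 entries were measured. Lists were tested with limma's camera at its preset correlation of 0.01, with camera's estimated correlation and with fry, which asks whether the genes of a list move on balance one way. Adjustment was over the lists of 1 comparison, and members were also adjusted over the list alone. Because changes followed the level of the genes, each median of the 3 genotype effects was also set beside 10000 random lists matched on level, a choice made after seeing the data.

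The text names genes by a rule fixed before the data were examined. For both knockout effects, the segment difference in wild-type and the difference between segments, these are up to 10 rises and 10 falls by size among called genes whose groups do not overlap, filled to 5 per direction by the smallest unadjusted p and then given as values only. Predicted genes, microRNA, small nucleolar RNA, olfactory and vomeronasal receptor genes were left out of that ranking. A fixed set of 19 vessel wall genes, the sex-linked genes, and up to 4 members with the smallest p in each called list were added.

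The alternatives were centring each array on its median, a second quantile normalization, leaving out the dimmest 25% of genes, the mean of a gene's probe sets, every row of the table, the replicate number as a block, only the groups compared, limma's trend and robust options, array weights, an adjusted p under 0.1, and leaving out each array in turn. After seeing the data, a fit without both wild-type replicate 2 arrays, whose value distributions were narrower, was added. The alternatives planned for the targeted gene were not run.

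The procedure was tested on simulated values with each gene's mean and its spread from the fit. Values were drawn independently, with 1 spread per gene for all groups. Differences in spread between groups and correlation between genes were therefore left out. In the averaged knockout effect it recovered 56.7% of 67 genes changed by 1 on the log2 scale and 100% of 67 genes changed by 2, among 22180, with 17 false calls. In the ascending effect it recovered 14.9% and 85.1%, and 100% of 66 genes changed by 3. In simulated data without correlation between genes, camera called 3.5% of 200 unchanged lists at an unadjusted p under 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.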

Results

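Gene expression was measured in the thoracic aorta of newborn mice (postnatal day 0) that lacked fibulin-4, a matrix protein needed to assemble elastic fibres, and in wild-type mice. The aorta was divided into an ascending segment, from the aortic valve to the ductus arteriosus, and a descending segment. Tissue of the same genotype and segment was pooled from 8 pups, and 2 such pools were hybridised per group, which gave 8 arrays in 4 groups. The labels call the arrays of a group biological replicates, so the spread between them includes the spread between pools.

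The deposited log2 values had a median between 4.68 and 4.89 on the 8 arrays. Among the 22180 genes with a name, the interquartile range was 1.80 in wild-type ascending replicate 2 and 1.74 in wild-type descending replicate 2, and lay between 2.14 and 2.28 on the other 6 arrays. Spearman's rho between the replicates of a group, across genes, was 0.899 in wild-type ascending, 0.929 in wild-type descending, 0.962 in knockout ascending and 0.966 in knockout descending aorta. The first principal component, with 29.4% of the variance, set both narrow wild-type arrays (scores -50.3 and -52.8) apart from the other 6, which scored between 9.81 and 26.5. The second, with 21.3%, set wild-type ascending replicate 1 apart, at 65.0 against -19.6 to 4.74 on the other 7 arrays. The number of arrays limits the precision: the median standard error of a log2 change was 0.30 within a segment and 0.21 averaged over segments. The targeted gene was not analysed here, so the genotype labels were not checked against it. Among sex-linked genes, Xist, which is transcribed from the inactive X chromosome, had a log2 value of 6.39 in wild-type descending replicate 2 and 7.28 in knockout descending replicate 2, against 8.55 to 9.28 on the other 6 arrays. The Y-linked gene Eif2s3y had 7.50 in knockout descending replicate 2 and 5.05 to 5.71 on the other 7 arrays.

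The first question was which genes differ between knockout and wild-type aorta when both segments are averaged. Col8a1, which encodes a short-chain collagen of the vessel wall, rose most: its log2 value was 5.09 ± 0.08 and 5.30 ± 0.74 (SD, n = 2) in wild-type ascending and descending aorta and 8.44 ± 0.31 and 8.82 ± 0.16 in the knockout, a log2 change of 3.44 (SE 0.25), or 10.8-fold. Thbs1, which encodes the matrix protein thrombospondin 1, an activator of latent TGF-beta, rose by 2.54 (SE 0.26), and Serpina3n, a serine protease inhibitor, rose by 2.26 (SE 0.21). The fibrillar and fibril-associated collagen genes Col11a1 (1.85, SE 0.18) and Col12a1 (1.59, SE 0.17) rose, as did Itga11 (1.91, SE 0.25), an integrin subunit that binds collagen. The secreted factors and binding proteins Igfbp2 (2.41), Adm (1.82) and Vegfd (1.67), the metallothionein Mt2 (1.64) and the genes Cd109 (1.90), Itgbl1 (1.77), Ahnak2 (1.60), Errfi1 (1.52) and Svep1 (1.49) completed the 15 genes that rose. The olfactory receptor gene Olfr507 was the 1 gene that fell, with a log2 change of -1.79. These 16 genes had limma adjusted p under 0.05 among the 22180 tested, with the smallest adjusted p at 0.00280 for Col8a1 and 0.0358 for Adm at the other end, and were chosen after their values were seen. In every one of these genes both knockout arrays of a segment lay on the same side of both wild-type arrays of that segment. The call of Olfr507 ended with each array centred on its median and after quantile normalization. Those of Adm and Errfi1 also ended after quantile normalization, and those of Ahnak2 and Svep1 with the mean of a gene's probe sets.

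**Figure D1:**
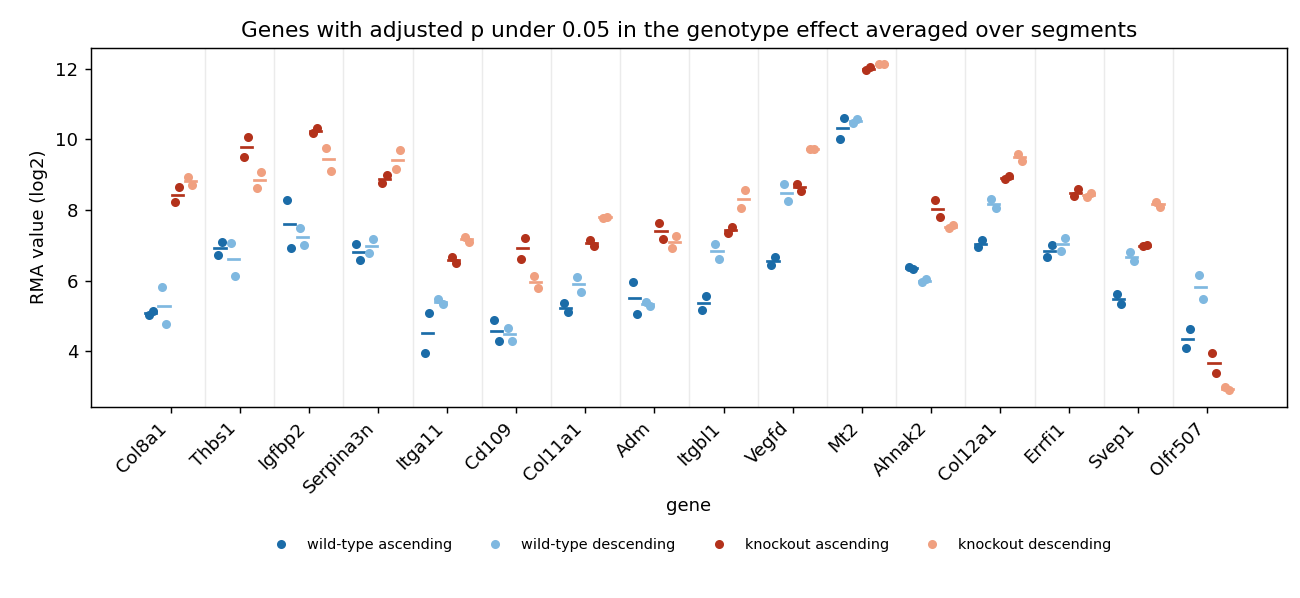
Deposited log2 values of the 16 genes called in the genotype effect averaged over segments, one point per array (2 per group) and a line at each group's mean. In 15 genes both knockout arrays lie above both wild-type arrays of the same segment, and in Olfr507 they lie below, with the largest difference in Col8a1 (log2 change 3.44).

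With an unadjusted p under 0.05 there were 2528 genes, 1678 higher and 850 lower in the knockout, where 1109 would be expected by chance. The count of 16 depended on single arrays: it was 50 without wild-type ascending replicate 1, 2 without wild-type descending replicate 1, 4 without wild-type descending replicate 2, 1 without knockout ascending replicate 1, 0 without knockout ascending replicate 2, 1 without either knockout descending array, and 25 without both narrow wild-type arrays. The genes called in those fits were not always among the 16. Without both narrow wild-type arrays Adm, Ahnak2, Cd109 and Svep1 were not called, and without wild-type descending replicate 2 Olfr802 and Ucp1 were. All 16 genes kept their direction in each of those fits. That was fixed in advance, because their knockout and wild-type arrays did not overlap within a segment. When all 41345 probe sets were tested, most of the added ones without a gene name, 1 was called, a probe set without a gene name, and none of the 16 genes; the adjusted p of Col8a1 was then 0.0905 and those of the other 15 lay between 0.233 and 0.338. The changes also followed the level of the genes: the median log2 change ran from -0.14 in the dimmest 20% of genes to 0.24 in the brightest 20%, so the lists of the 3 genotype effects are set beside random lists of the same levels; those of the segment differences and of the difference between segments were not.

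Over both segments 23 of the 46 gene lists were called by limma's camera test, 20 higher and 3 lower in the knockout; 13 of the higher and 3 of the lower ones lay outside the central 95% of level-matched random lists. In the list of integrins and adhesion proteins 27 of 28 measured members lay above 0, the median change was 0.46, and 12 members passed when adjusted over the list alone. Examples are Itga11, Itga5 (1.35), a fibronectin receptor subunit, and Fn1 (0.90), which encodes fibronectin. Its adjusted p was 0.186 with an estimated correlation. Of the genes that respond early to mechanical load and growth factors, 20 of 20 lay above 0 with a median of 0.70, and 9 passed when adjusted over the list alone, among them Ankrd1 (2.30) and Ccn1 (1.63); the adjusted p was 0.217 with an estimated correlation, and the median was 0.39 without both narrow wild-type arrays. Collagen-modifying enzymes had a median of 0.55, with 8 of 17 passing when adjusted over the list alone, including the hydroxylases Plod2 (1.31) and P4ha1 (1.14), and an adjusted p of 0.217 with an estimated correlation. Matrix proteases had a median of 0.37 and 8 of 26 members passing over the list alone, with an adjusted p of 0.186 with an estimated correlation. Level-matched random lists had medians of 0.21, 0.17, 0.19 and 0.11 for these 4 lists, and each list lay at or above the 99th percentile of them. No list was called in any comparison with an estimated correlation, and fry called 14 lists here. The 3 lower lists were markers of skeletal muscle (median -0.45), adipocytes (-0.41) and endothelium (-0.24), and myeloid markers (0.57) were among the higher ones. The skeletal muscle median was -0.21 without wild-type ascending replicate 2. The endothelial call ended without replicate 1 of wild-type ascending (-0.27) or descending (-0.19) aorta. It also ended without replicate 2 of knockout ascending (-0.17) or descending (-0.22) aorta.

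The second question was what the knockout changed in the ascending aorta. Markers of myeloid cells were higher as a group in the knockout, with 24 of 26 above 0, a median log2 change of 0.73 against 0.16 in level-matched random lists, and 9 passing when adjusted over the list alone. Examples are Laptm5 (1.68, SE 0.30), Fcer1g (1.32, SE 0.30), Itgam (1.23, SE 0.28) and the macrophage marker Adgre1 (1.14, SE 0.25). The early response genes were also higher as a group, with 19 of 20 above 0, a median of 0.84 and 10 passing over the list alone. Ankrd1 stood at 2.83 (SE 0.50), Ier3 at 2.02 (SE 0.42) and Ccn1 at 1.98 (SE 0.45). Skeletal muscle markers were lower as a group, with 24 of 25 below 0, a median of -0.83 and 9 passing over the list alone, among them Mylpf (-2.93, SE 0.73) and Ckm (-2.12, SE 0.42). The mean deviation of these markers from their mean over all arrays was 0.40 and 1.24 in the wild-type and 0.01 and -0.37 in the knockout ascending arrays, and the median change was -1.29 without wild-type ascending replicate 1 and -0.42 without replicate 2. Each of these 3 lists had adjusted p = 0.237 with an estimated correlation.

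In the ascending aorta 8 of 28 integrin and adhesion genes passed when adjusted over the list alone (median 0.44; Itga5 1.76, SE 0.27), as did 5 of 24 genes of the response to low oxygen and of glycolysis (median 0.54; Hmox1 2.07, SE 0.39). So did 5 of 17 TGF-beta target genes (median 0.55; Ccn2 1.48, SE 0.35) and 6 of 17 genes of cholesterol synthesis (median 0.52; Hmgcs1 1.54, SE 0.31, a step before the rate-limiting reductase). These 4 lists had adjusted p = 0.237 with an estimated correlation. The chemokine and cytokine list had a median of 0.39, with Ccl7 at 1.39, Ccl2 at 1.36 and Cxcl13 at 1.34, and the complement and coagulation list 0.34, with C4b at 1.47. Both had adjusted p = 0.237 with an estimated correlation. Without wild-type ascending replicate 2 the complement median was 0.22 and that of the low oxygen list 0.35, both still called. All 22 genes of the unfolded protein response lay above 0 with a median of 0.44 and none passed over the list alone (adjusted p = 0.247 with an estimated correlation). Endothelial markers were lower as a group (15 of 20 below 0, median -0.63), with Egfl7 at -1.19 and Cldn5 at -1.21, while Flt1, a VEGF receptor, stood at 1.24; the adjusted p was 0.486 with an estimated correlation, and the median was -0.41 without knockout ascending replicate 2. The elastic fibre list had a median of 0.25, at the 78.5th percentile of level-matched random lists, and 0 of 22 members passed over the list alone (adjusted p = 0.486 with an estimated correlation); its call ended after quantile normalization (0.18). The contractile smooth muscle list had a median of 0.22, at the 61.3rd percentile (adjusted p = 0.486 with an estimated correlation). Its call ended without wild-type ascending replicate 1 (0.27), without knockout ascending replicate 2 (0.15), after quantile normalization (0.10) and without the dimmest 25% of genes.

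Among genes fixed in advance for the vessel wall, the ascending log2 change was 0.19 (SE 0.24) for Eln, which encodes elastin, 0.15 for the smooth muscle actin gene Acta2, 0.13 for Col3a1, 0.29 for Fbln5, and 0.80 (SE 0.27) for Lox, the enzyme that cross-links elastin and collagen. Thbs1 stood at 2.86 (SE 0.36), Egr1, an immediate early transcription factor, at 1.63 (SE 0.52), and Ace, the angiotensin-converting enzyme, at 0.14 (SE 0.24). No single gene was called in the ascending aorta by limma: the smallest adjusted p was 0.0780, for Col8a1 (log2 change 3.35, SE 0.35), and 1975 genes had an unadjusted p under 0.05, 1177 higher and 798 lower, against 1109 expected by chance. The count was 11 without wild-type ascending replicate 1, 14 without wild-type ascending replicate 2, 1 without either wild-type descending array, and 11 without both narrow wild-type arrays. Of the 21 lists called here (17 higher, 4 lower), 11 of the higher and 3 of the lower ones lay outside the central 95% of level-matched random lists, and 16 stayed called whichever single array was left out.

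The same question was asked of the descending aorta. Col8a1 rose there by 3.53 (SE 0.35), or 11.5-fold, and was the only gene called (limma adjusted p = 0.0494). Adipocyte markers were lower as a group in the knockout, with 17 of 20 below 0, a median of -0.55 and 6 passing when adjusted over the list alone. Ucp1, the uncoupling protein of brown fat, stood at -3.35 (SE 0.50), Cox8b at -2.35 (SE 0.52) and Pck1 at -1.50 (SE 0.32). Collagen-modifying enzymes were higher as a group, with 16 of 17 above 0, a median of 0.72 and 9 passing over the list alone, among them Plod2 (1.29, SE 0.32) and Serpinh1 (0.95, SE 0.27), a chaperone of collagen. Collagens had a median of 0.53 and 3 of 19 passing over the list alone, and the elastic fibre list a median of 0.40 with 2 of 22 passing, Fbn2 (1.75, SE 0.26) and Ltbp2 (1.26, SE 0.25) having the smallest p. Each of these 4 lists had adjusted p = 0.229 with an estimated correlation, and the collagen median was 0.34 without knockout descending replicate 1.

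Markers of cardiomyocytes were higher as a group in the knockout descending aorta (median 0.53, 19 of 23 above 0), with Myl7 at 2.28 (SE 0.63) and Tnnc1 at 2.05 (SE 0.41), and TGF-beta targets had a median of 0.56 with Thbs1 at 2.22 (SE 0.36); both lists had adjusted p = 0.229 with an estimated correlation. Cell cycle genes had a median of 0.51 with 31 of 33 above 0, and Birc5 stood at 1.26 and Cdk1 at 1.15 (adjusted p = 0.385 with an estimated correlation). Without wild-type descending replicate 2 the cell cycle median was 0.24 and that of the TGF-beta targets 0.29, both still called. Early response genes (median 0.61) and matrix proteases (0.33) were also called higher, but not with an estimated correlation. Both of these calls ended without wild-type descending replicate 2, with medians of 0.29 and 0.21. The rise of these 2 lists in the descending aorta thus leaned on that 1 array. Myeloid markers had a median of 0.39, and the 1 member that passed over the list alone, the neutrophil marker Ly6g, was lower at -2.31 (SE 0.36), opposite to the list; the adjusted p was 0.385 with an estimated correlation. The myeloid call ended without knockout descending replicate 1 (median 0.16), and the median was 0.61 without knockout descending replicate 2. The clock gene list had a median of 0.37, with Arntl at 1.26 and Per1 at 1.03 (adjusted p = 0.385 with an estimated correlation), and its call ended without wild-type descending replicate 2 and without both narrow wild-type arrays (median 0.20 in each).

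In the descending aorta Eln stood at 0.13 (SE 0.24), Acta2 at -0.02, Lox at 0.83 (SE 0.27) and Ace at 0.56 (SE 0.24), none called. With an unadjusted p under 0.05 there were 1319 genes, 805 higher and 514 lower. The call of Col8a1 was lost in 11 of 17 alternatives, with adjusted p from 0.0160 to 0.358; it held without wild-type descending replicate 1 (0.0356) and was lost without wild-type ascending replicate 1 (0.0501) and replicate 2 (0.0501). It was 0.0792 without wild-type descending replicate 2 (where 2 other genes were called), 0.208 without either knockout ascending array, 0.338 without knockout descending replicate 1 and 0.358 without knockout descending replicate 2; without both narrow wild-type arrays it was 0.0468 and 7 genes were called. Of the 24 lists (21 higher, 3 lower), 16 of the higher and 3 of the lower ones lay outside the central 95% of level-matched random lists. Of all 24, 10 stayed called whichever single array was left out, 15 stayed without wild-type descending replicate 2 and 14 without both narrow wild-type arrays.

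**Figure D2:**
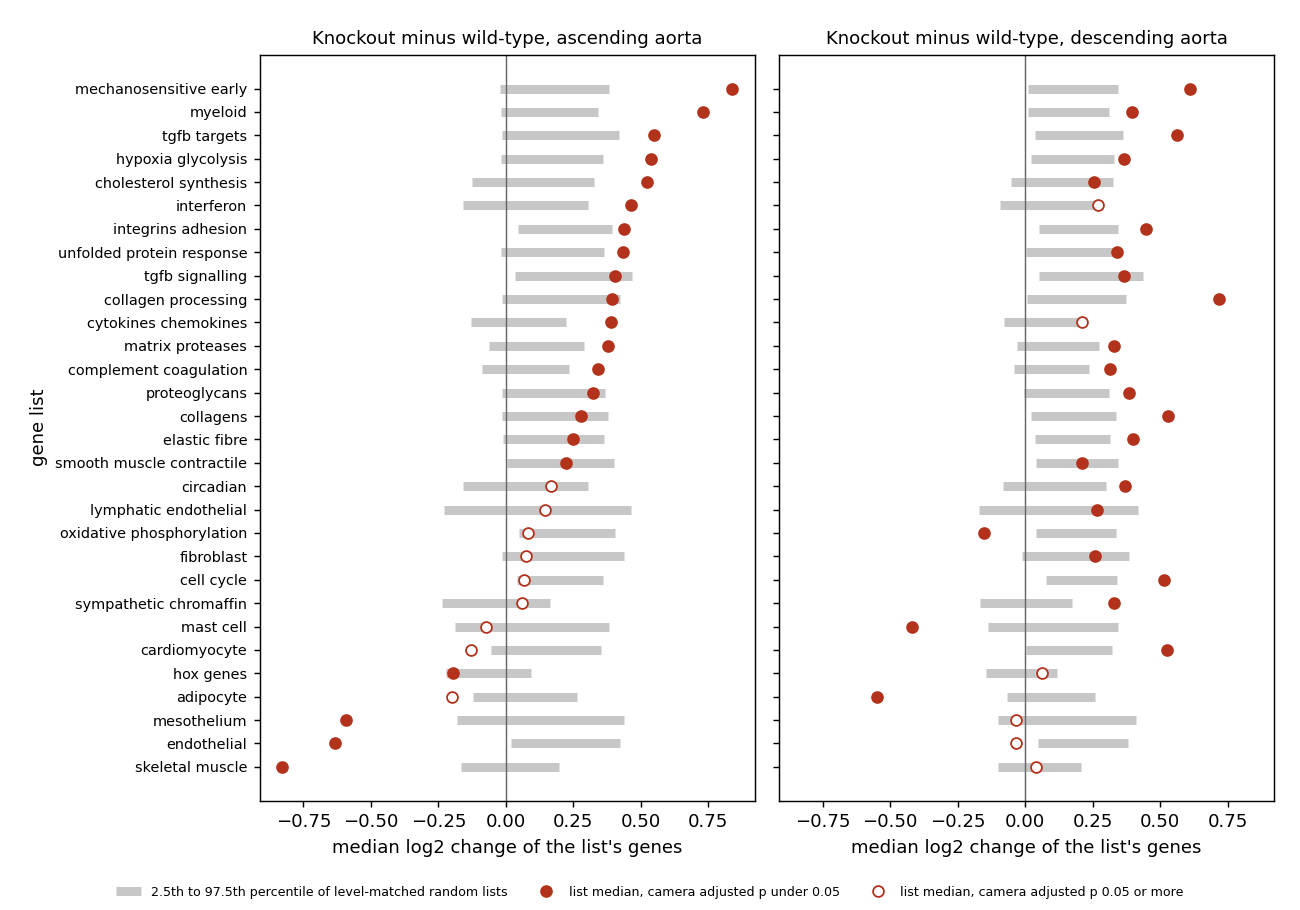
Median log2 change (knockout minus wild-type) of the genes of each list called by camera in the ascending or the descending aorta, with filled points for lists called in that segment and grey bars for the central 95% of 10000 random lists matched on level. The ascending myeloid median (0.73) and the descending collagen processing median (0.72) lie above their bars, and the ascending skeletal muscle median (-0.83) lies below its bar.

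Whether the segments responded alike was asked across genes. The log2 changes in ascending and descending aorta, which share no array, had a Pearson correlation of 0.305 and a Spearman correlation of 0.319 across 22180 genes, and 61.3% of genes had the same sign. Genes are not independent replicates. Of the genes with unadjusted p under 0.05, 227 were higher in both segments where 42.7 would be shared by independent lists and 74.3 by lists independent among genes of like level, and 44 were lower in both, where 18.5 and 25.2 would be. Without both narrow wild-type arrays 170 were higher in both and 123 lower, where 71.6 and 66.3 would be shared among genes of like level. The comparison by level and that fit were chosen after seeing the data. The correlation was 0.0812 without both narrow wild-type arrays, 0.0828 without wild-type ascending replicate 2, 0.144 without wild-type descending replicate 2, and 0.405 without wild-type ascending replicate 1.

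The test of the difference itself called 0 genes by limma (smallest adjusted p 0.523), with 733 at an unadjusted p under 0.05 against 1109 expected by chance. By camera 11 lists differed between the segments in their genotype effect. The effect was lower in ascending than in descending aorta for skeletal muscle markers (median difference -0.78, 6 of 25 passing over the list alone; Mylpf -3.91, SE 1.03) and for cardiomyocyte markers (-0.95; Ttn -2.30, SE 0.56), with adjusted p = 0.605 with an estimated correlation for both. It was higher in ascending aorta for myeloid markers (0.55; Fcer1g 1.14, SE 0.42) and adipocyte markers (0.50; Ucp1 2.61, SE 0.70), and lower for endothelial markers (-0.54; Emcn -1.03, SE 0.33), with adjusted p = 0.659 with an estimated correlation for all 3. The skeletal muscle and cardiomyocyte lists stayed called whichever array was left out, with medians of -1.40 and -0.50 for skeletal muscle without wild-type ascending replicate 1 and 2 and of -0.53 and -0.62 for cardiomyocyte markers without wild-type descending replicate 2 and without both narrow wild-type arrays. The myeloid and adipocyte calls ended without wild-type ascending replicate 2 (0.24 and 0.44). The myeloid median was 0.36 without knockout ascending replicate 1 and 0.29 without both narrow wild-type arrays, and the adipocyte median was 0.28 and 0.80 without wild-type descending replicate 1 and 2. The endothelial call ended without wild-type descending replicate 2 (-0.37) and without both narrow wild-type arrays (-0.56); the median was -0.82 without wild-type descending replicate 1 and -0.36 without knockout ascending replicate 2.

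The last question was how the segments differ within a genotype. In wild-type aorta Tcf21, a transcription factor of epicardial and fibroblast lineages, was higher in the ascending segment by 3.01 (SE 0.32): 7.62 ± 0.61 against 4.62 ± 0.14 (SD, n = 2). Cxcl13, a chemokine gene that attracts B cells, was lower there by a log2 change of -2.79 (SE 0.28), with 6.55 ± 0.26 against 9.33 ± 0.31 (SD, n = 2). Both were called by limma at adjusted p = 0.0421, and Ptn, which encodes a secreted growth factor, followed at 2.43 (SE 0.28) with adjusted p = 0.0530. With the replicate number as a block, Tcf21 kept its call (limma adjusted p = 0.0481) and Cxcl13 lost it (0.0667). With array weights both genes lost their call (limma adjusted p = 0.1155 for each). Skeletal muscle markers were higher as a group in wild-type ascending aorta, with 23 of 25 above 0, a median of 0.87 and 13 passing over the list alone. Tnnt3 stood at 2.94 (SE 0.47) and Acta1 at 3.22 (SE 0.62). Adipocyte markers were lower as a group, with a median of -1.03 and 10 of 20 passing over the list alone, among them Ucp1 (-2.86, SE 0.50). Both lists had adjusted p = 0.361 with an estimated correlation. The skeletal muscle median was 1.47 without wild-type ascending replicate 1 and the adipocyte median -0.58 without wild-type descending replicate 1. Endothelial markers (median -0.41) and complement and coagulation genes (-0.31) were also called lower by camera, but not with an estimated correlation. The endothelial median was -0.30 without wild-type ascending replicate 2 and -0.11 without wild-type descending replicate 1. The complement median stayed between -0.37 and -0.25 in the fits without an array.

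Mast cell markers were lower in wild-type ascending aorta (0 of 10 above 0, median -0.51), with Mcpt4 at -2.29 (SE 0.38). Genes of the outflow tract and neural crest, most of them transcription factors, had a median of 0.16 with 4 of 26 passing over the list alone. Hand2 stood at 1.22, Tbx20 at 1.08 and Dlx6 at 1.02. Both lists had adjusted p = 0.594 with an estimated correlation. The mast cell call ended without wild-type ascending replicate 2 (-0.37; -0.78 without replicate 1). The outflow tract call ended without wild-type ascending replicate 1 (0.09) or 2 (0.28), without wild-type descending replicate 2 (0.06) and without both narrow wild-type arrays (0.16); the median was 0.28 without wild-type descending replicate 1. Lung epithelium markers had a median of 0.42 and Hox genes, which mark position along the body axis, -0.13 (Hoxa5 -1.59, SE 0.45; Hoxb6 -1.23, SE 0.27), both with adjusted p = 0.644 with an estimated correlation. The surfactant gene Sftpc had log2 values of 9.71 and 6.19 in wild-type ascending and 4.56 and 6.01 in wild-type descending replicates 1 and 2. The lung call ended without wild-type ascending replicate 1 (0.37) or 2 (0.56) and without wild-type descending replicate 1 (0.27). The Hox call ended without wild-type ascending replicate 2 (-0.04), without wild-type descending replicate 1 (-0.05), without both narrow wild-type arrays (-0.18), after quantile normalization (-0.17) and without the dimmest 25% of genes; the median was -0.34 without wild-type ascending replicate 1 and -0.28 without wild-type descending replicate 2. Without wild-type ascending replicate 2 the count of called genes was 23, both genes among them, and 4 of the 14 lists stayed called. Without wild-type ascending replicate 1 the count was 3, neither gene among them, and it was 0 without any other array and 9 without both narrow wild-type arrays. The adjusted p over 17 alternatives ran from 0.00756 to 0.425 for Tcf21 and from 0.0224 to 0.425 for Cxcl13.

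In knockout aorta endothelial markers were lower as a group in the ascending segment, as they were in wild-type aorta (median -0.41). In the knockout 0 of 20 lay above 0, with a median of -0.76 and 9 passing over the list alone. Among them were Vwf (-1.78, SE 0.26), the gene of von Willebrand factor, and Ptprb (-1.27, SE 0.26). Hox genes were lower as a group, with 5 of 28 above 0, a median of -0.37 and 8 passing over the list alone, among them Hoxc6 (-2.06, SE 0.37) and Hoxb8 (-1.74, SE 0.36). Both lists had adjusted p = 0.397 with an estimated correlation. Early response genes were higher as a group (median 0.61, 17 of 20 above 0; Ccn2 0.94, SE 0.35), with adjusted p = 0.487 with an estimated correlation; the median was 0.25 without knockout descending replicate 1. Lung epithelium markers had a median of 0.15 and 3 of 13 passing over the list alone, Scgb1a1 standing at 2.44 (SE 0.49), with adjusted p = 0.475 with an estimated correlation. Their call ended without knockout descending replicate 2 (0.02), and the median was 0.25 without knockout descending replicate 1. No single gene was called by limma (smallest adjusted p 0.0621), and 895 genes had an unadjusted p under 0.05 against 1109 expected by chance. The shared spread includes the wild-type arrays, whose replicates differed more. The median absolute difference between replicates was 0.39 and 0.34 in wild-type ascending and descending aorta, and 0.25 and 0.23 in knockout. With array weights some genes were called, so the lack of calls does not show that single genes were alike.

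**Figure D3:**
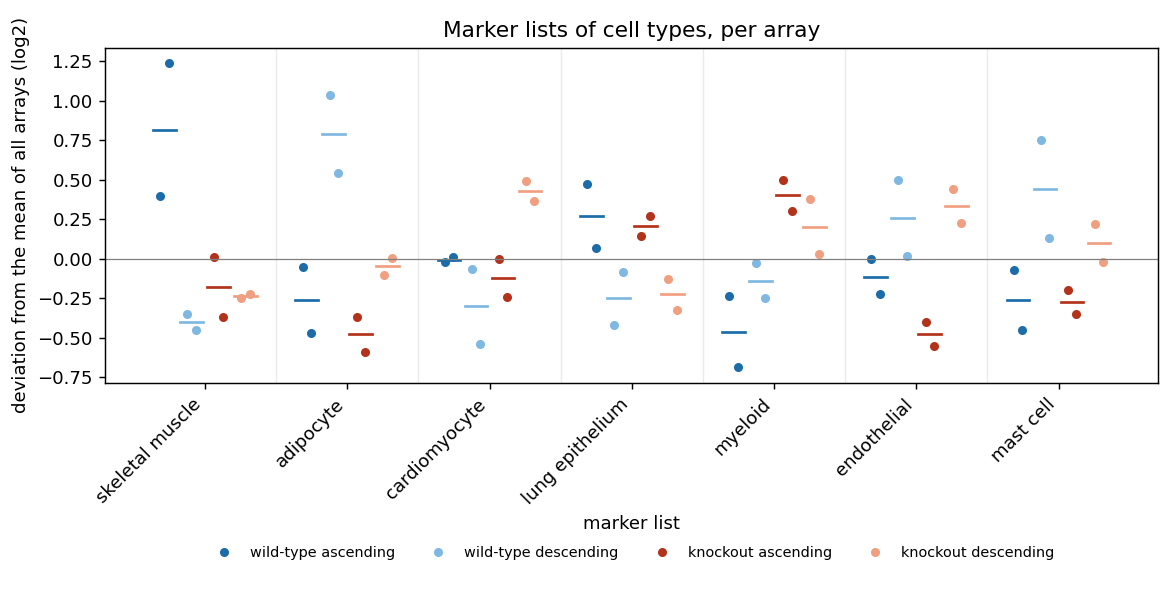
Mean deviation of 7 marker lists from their mean over all arrays (log2), one point per array, 2 per group, with a line at the mean of each group. Skeletal muscle markers reach 1.24 in wild-type ascending replicate 2 and adipocyte markers 1.04 in wild-type descending replicate 1, and both knockout ascending arrays have endothelial markers at or below -0.40.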

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

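The test of a lower share of the main cell type, the fit without both narrow wild-type arrays and the correlation of the myeloid and endothelial markers between replicates were chosen only after the result was seen.

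The genotype effect differed between segments for 11 gene lists by camera, none with an estimated correlation (adjusted p from 0.605 to 0.702). The median difference, ascending minus descending, was -0.95 for cardiomyocyte, -0.78 for skeletal muscle, -0.54 for endothelial, -0.33 for sympathetic and chromaffin, -0.29 for cell cycle and -0.15 for Hox genes. It was 0.55 for myeloid, 0.50 for adipocyte, 0.36 for early response, 0.24 for cytokine and chemokine and 0.17 for oxidative phosphorylation genes. Of the 11 lists 2, skeletal muscle and cardiomyocyte, stayed called whichever array was left out. The early response call ended without wild-type ascending replicate 2 (0.44), wild-type descending replicate 1 (0.10) or knockout descending replicate 1 (0.04). It held with medians of 0.80 without wild-type descending replicate 2, 0.74 without knockout descending replicate 2 and 0.70 without both narrow wild-type arrays. The cytokine call ended without wild-type ascending replicate 2 (0.19), wild-type descending replicate 2 (0.20) or both narrow arrays (0.04), and held at 0.43 without wild-type ascending replicate 1, 0.15 without knockout ascending replicate 2 and 0.13 without knockout descending replicate 2. The oxidative phosphorylation median turned to -0.09 without wild-type descending replicate 1, where its call ended. That call also ended without wild-type ascending replicate 2 (0.04), knockout ascending replicate 1 (0.13), knockout descending replicate 2 (0.12) or both narrow arrays (0.19), and after quantile normalization (0.09). It held at 0.34 without wild-type ascending replicate 1, 0.36 without wild-type descending replicate 2 and 0.26 without knockout descending replicate 1. The cell cycle call ended without wild-type ascending replicate 1 (-0.11), wild-type descending replicate 2 (-0.15) or both narrow arrays (-0.20), and held at -0.51 without wild-type ascending replicate 2 and -0.56 without wild-type descending replicate 1. The Hox call ended without wild-type ascending replicate 1 (-0.11), wild-type descending replicate 2 (-0.23), knockout ascending replicate 1 (-0.09), knockout descending replicate 1 (-0.07) or both narrow arrays (-0.30). It held at -0.34 without wild-type ascending replicate 2 and -0.33 without wild-type descending replicate 1. The sympathetic call ended without wild-type ascending replicate 2 (-0.27), wild-type descending replicate 1 (-0.33), either knockout ascending array (-0.41 and -0.51), knockout descending replicate 1 (-0.42) or both narrow arrays (-0.30), and after quantile normalization (-0.37). It held at -0.52 without wild-type descending replicate 2, -0.65 without knockout descending replicate 2 and -0.49 without the dimmest 25% of genes. Among probe sets without a gene name here, 1 was called when every row was tested: its averaged log2 change was -3.02 (SE 0.17, limma adjusted p = 0.0193), with values of 8.28 to 8.43 on the wild-type and 5.13 to 5.66 on the knockout arrays.

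The 16 genes called in the averaged genotype effect were set against 3 technical explanations. In a fit of 2 groups without the segment, the split by genotype called 10 genes and the highest other split of the 8 arrays called 2. So 1 split of 35 was as large, the smallest share that 35 splits can give. Both narrow arrays are wild-type, so the arrays are not interchangeable and chance is not excluded. By unadjusted p under 0.05 the counts were close, with 2540 genes against 2457 in the highest other split. Without both narrow wild-type arrays the changes kept a median of 0.976 of their size, from 0.810 for Igfbp2 to 1.13 for Itga11. These genes were called on the same arrays because their changes were large against the spread between replicates. A ratio near that of the full fit was therefore likely, and it does not decide whether the narrow arrays contributed. All 16 genes kept their direction, which could not turn because their knockout and wild-type arrays did not overlap within a segment. Among the 40 measured genes next to the targeted gene, 5% had an unadjusted p under 0.05, against a 95th percentile of 20% for windows of the same size. So these neighbours held no excess of changed genes. Of the 16 genes 0 were among them, which was likely under any cause because 40 is a small part of the genes tested. Flanking DNA of another strain that acts on distant genes would leave no such trace, so it is not excluded for the 16 genes. A response of the vessel wall to the knockout remains a hypothesis, found and tested on the same arrays, and a processing batch that follows the genotype was not tested.

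Skeletal muscle markers were high in wild-type ascending aorta, which enters both the lower values of the knockout ascending aorta and the segment difference in wild-type. A candidate explanation is muscle carried over in the dissection. The markers' differences between replicates went together, with a mean pairwise correlation of 0.253 against a 95th percentile of 0.0765 in 1000 level-matched random lists. Myeloid markers also passed that test (0.283 against 0.215), so it cannot tell carried-over muscle from another source of muscle cells. Acta1, the brightest of the 25 markers, had log2 values of 9.48 and 11.11 in the wild-type ascending pools and 6.75 to 8.88 in the other 6; 12 of the markers lie above the median gene and 0 are in another list. A difference between the genotypes in muscle around the ascending aorta was not tested and stays open.

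Myeloid markers were higher and endothelial markers lower in knockout ascending aorta. A lower share of the main cell type, acting alone, would move both alike. The endothelial median lay below the myeloid median (difference -1.37, 2 SE 0.503), which restates the pattern that was seen first. It is therefore no independent test, and a lower share together with a separate fall of endothelial markers is not excluded. The joint median of red cell and platelet markers also lay below the myeloid median (difference -0.62, 2 SE 0.432). Each SE is over the genes of the lists, not over pools, and genes of a list are not independent. Blood left in the vessel is not excluded. Of globin genes the red cell list holds only the embryonic Hbb-y and Hba-x, beside other red cell genes such as Slc4a1. The myeloid list includes the neutrophil marker Ly6g. The platelet median alone was 0.22. The differences of the myeloid markers between replicates also went together (mean pairwise correlation 0.283, 95th percentile of random lists 0.215), and for the endothelial markers the correlation lay below that percentile (0.298 against 0.363). Of the 26 markers 22 lie above the median gene and 4 are in another list, and the brightest, S100a8, had log2 values of 11.04 and 10.85 in knockout and 9.61 and 7.44 in wild-type ascending aorta. More myeloid cells, or more transcript per cell, may account for the higher myeloid markers and cannot be separated by these arrays. The cause of the lower endothelial markers stays open.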

How the results depend on the processing

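The fits without both wild-type replicate 2 arrays and the second quantile normalization of list tests and of the correlation were chosen after seeing the data, as were all alternatives for the overlap of the genotype effects. The cause of the changes below was not tested. The alternatives planned for the targeted gene were not run, and signal over background was not measured here. Where an array is left out, the remaining array of its group is assumed to vary like the other groups. Called genes in ascending aorta were 0, but 1 without dim genes, 4 with trend and robust options, 11 without both wild-type replicate 2 arrays and 1 at an adjusted p under 0.1. In descending aorta there was 1, but 0 with centring, quantile normalization, the replicate block, only the groups compared or every row; 2 without dim genes, with array weights and at an adjusted p under 0.1; 4 with trend and robust options; and 7 without both wild-type replicate 2 arrays. The averaged effect gave 16, but 35 without dim genes, 25 without both wild-type replicate 2 arrays, 1 with every row (none of the 16) and 50 at an adjusted p under 0.1. The segment difference in wild-type gave 2, but 1 with centring or the replicate block, 0 with only the groups compared, array weights or every row, and 9 without both wild-type replicate 2 arrays. The segment difference in knockout gave 0, but 2 without dim genes, with trend and robust options and at an adjusted p under 0.1, and 18 with array weights; the interaction gave 0, but 1 without both wild-type replicate 2 arrays.

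The replicate block left 0 genes in ascending aorta and 19 in the averaged effect; same-numbered arrays deviated together at a correlation of 0.292 in the wild-type pair and from -0.0778 to 0.116 in the others. With an estimated correlation 0 lists were called in each comparison; fry called 7 in ascending aorta, 2 in descending aorta, 14 averaged and 0 in both segment differences and the interaction. In descending aorta 15 lists were called without both wild-type replicate 2 arrays. After quantile normalization 90% of the 20 lists higher in the averaged effect stayed called. The correlation of the genotype effects was 0.227 after quantile normalization and 0.0812 without both wild-type replicate 2 arrays, where the overlap in genes lower in knockout went from 44 to 123.

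Leaving out each array in turn, called genes ranged from 0 to 14 in ascending aorta, 0 to 2 in descending aorta, 0 to 50 averaged, 0 to 23 for the segment difference in wild-type, and stayed at 0 for the segment difference in knockout and the interaction. Called lists ranged from 18 to 21, 16 to 24, 21 to 27, 4 to 15, 11 to 14 and 6 to 12 in the same order, and the correlation from 0.0828 to 0.405. The overlap ranged from 114 to 416 genes higher and from 21 to 175 genes lower in knockout. In the segment difference in wild-type, early response genes (mechanosensitive) had a median of 0.12, 0.432 without wild-type descending replicate 1 and, reversed, -0.201 without wild-type descending replicate 2; cardiomyocyte markers went from 0.11 to 0.0321 without both wild-type replicate 2 arrays, where the test turned direction and the call ended. The cardiomyocyte call also ended with the replicate block, without wild-type descending replicate 2, where the median turned to -0.09, and without wild-type ascending replicate 2 (0.10). It held at 0.52 without wild-type ascending replicate 1, 0.37 without wild-type descending replicate 1 and 0.17 after quantile normalization. Over all alternatives, 9345 values of named genes kept their direction and their side of the threshold, 48 newly passed, 133 no longer passed and 89 changed sign with no call on either side.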

Other observations

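Red cell markers had a median log2 change (knockout minus wild-type) of 0.00 in ascending and -0.02 in descending aorta, and ribosomal protein genes stood at -0.01 and 0.05. Cartilage markers stood at -0.09 and 0.11 and potassium and calcium channel genes at -0.02 and 0.17, none called by camera. Notch pathway genes were lower as a group in the ascending segment of the knockout, with a median of -0.33 and 3 of 18 above 0 (adjusted p = 0.488 with an estimated correlation; the call ended without knockout descending replicate 1, where the median was -0.19).

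Adipocyte markers, which were lower in wild-type ascending than descending aorta and lower in the knockout descending aorta, had differences between replicates with a mean pairwise correlation of 0.206, against a 95th percentile of 0.138 in 1000 level-matched random lists. Their array means ran from -0.59 in knockout ascending replicate 2 to 1.04 in wild-type descending replicate 1, and Fabp4, the brightest of the 20 markers, had log2 values of 12.05 and 11.80 in wild-type descending aorta.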
